A study of Homo sapiens with 30 samples.

How the data were processed

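The series holds 1 table of 60591 gene symbols by 30 libraries, made from RNA of sorted cells or bulk tissue of head and neck squamous cell carcinomas. Per the submitters' processing notes, the tools were Trim Galore 0.6.5 with cutadapt, FastQC and kallisto 0.46.0; the genome build and annotation are not given in the sources used here. The deposited values are TPM, which have the same sum in each library, so the depth is unknown and no counting interval or floor was computed. No 2 columns were identical. Symbols were matched to GENCODE 29 for gene types only (55204 matched, 19559 protein-coding), and 502 rows of Y-linked genes, XIST and TSIX were left out.

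Groups came from the labels; the groups, fits, gene lists and rule for named genes were fixed before the data were examined. Libraries of the same tumour and population were averaged on the log scale, which gave 19 sorted samples, and 23 with bulk tissue. Each population was compared with the unweighted mean of the other 3, with tumour as a block, since populations of a tumour come from the same person. As a check, deviations from the population means in samples of the same tumour but different populations correlated at a mean r of 0.206 (19 of 23 above 0.1), against -0.04 for different tumours (109 comparisons). Bulk tissue was compared with the mean of the 4 populations without a block, as fixed beforehand. A fit of that comparison with the block was run first, by mistake; its gene names were replaced by those of the planned fit, and its count is given as an alternative. The bulk gene lists followed across settings and the tests of the immediate early list were picked after that first fit.

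Tests used limma 3.58.1 (R 4.3.3, statmod 1.5.0; eBayes with trend and robust) on log2(TPM + 1), for genes with TPM of at least 1 in at least 3 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. A gene was enriched if called higher and more than 1 log2 unit above each other population. Pairs of libraries were fitted with the pair as a block; 3 pairs had both methods stated and 4 had 1 not stated. The 7 pairs came from 5 tumours, so p-values over pairs treat pairs of the same tumour as separate. For the 34 gene lists, camera was run with its preset correlation of 0.01 and with an estimated one, and fry beside it. Mean list levels in pairs were tested by exact two-sided sign flips (128 arrangements), and bulk list levels by exact two-sided permutation.

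Named genes were chosen by a rule, which took up to 10 genes per direction with the largest fold change among those called, with a mean level in the upper part of the tested genes and the same direction in every tumour or pair; where too few passed, it was filled to 5 by smallest p, said not to pass. Up to 4 members of each list with the smallest p were added. Pseudogenes, unnamed genes, immunoglobulin and T cell receptor variable segments, Y-linked genes and XIST were left out.

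The fits were tested on simulated data drawn with the mean levels and spread of the real genes, in which 200 genes were changed by 1, 2 or 3 log2 units. The changed genes were picked from those with a mean level at or above the median. Genes were drawn independently, with the same change in every library of the group. No effect of a tumour or library was shared between genes, so recovery in the real data may be lower. Recovery was 25.4%, 77.6% and 87.9% for the tumour comparison, 23.9%, 82.1% and 89.4% for immune, 7.5%, 70.1% and 84.8% for endothelial, and 7.5%, 62.7% and 81.8% for fibroblast. It was 9.0%, 67.2% and 81.8% for the 7 pairs, and 0%, 3.0% and 30.3% for the 3 pairs. The bulk comparison was not simulated.

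Alternatives fixed with them were trimmed-mean scaling, quantile normalization, limma without trend and robust, no filter, a filter at 10 TPM, pseudocounts of 0.1 and 5, fits with and without blocks, every library as its own sample, array weights, libraries without enzymes in the label, and leaving out each tumour, pair or bulk library. Alternatives that need counts did not apply to TPM. Added after seeing the data were rescaling to equal protein-coding totals (mitochondrial genes left out of the total), and leaving out the library labelled endothelial of tumour C, the mechanical tumour-sorted library of tumour E, or bulk tissue of tumour G together with the rescaling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.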

Results

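RNA was profiled in 30 libraries from 8 head and neck squamous cell carcinomas, named here tumour A to H. The 26 sorted libraries came from 6 tumours and were labelled as immune (9 libraries, 6 tumours), tumour (8 libraries, 6 tumours), endothelial (5 libraries, 4 tumours) or fibroblast (4 libraries, 3 tumours). Another 4 libraries were unsorted bulk tissue of tumours A, F, G and H. The labels named enzymatic dissociation for 7 sorted libraries, mechanical dissociation for 3, both for 6 and no method for 10. The series compares ways of taking tissue apart, so the questions were which genes mark each sorted population, how bulk tissue differs from sorted cells, and what differs between libraries of the same tumour and population that were labelled with and without enzymes. The values were TPM, which keep no sequencing depth, so the depth of each library is unknown. Protein-coding genes held a median of 10.5% of the TPM (lowest 0.496%, in bulk tissue of tumour G; highest 28.5%), and 5.8S ribosomal RNA a median of 56.2%.

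Mean levels of each lineage list were highest in the samples labelled with that lineage, but single libraries departed from this. The epithelial list averaged 5.05 ± 1.02 (log2(TPM + 1), SD, n = 6 tumours) in tumour-sorted samples and 1.48 ± 0.70 (SD, n = 6) in immune-sorted samples. The immune list averaged 6.43 ± 0.31 (SD, n = 6) in immune-sorted samples, and the fibroblast list 7.68 ± 0.85 (SD, n = 3) in fibroblast-sorted samples. The library labelled endothelial of tumour C had an endothelial list level of 0.65 and a fibroblast list level of 7.74, while the other endothelial libraries lay between 5.1 and 5.8 on the endothelial list. The 4 libraries whose values correlated best with it across genes were the 4 fibroblast-sorted ones (r = 0.867 to 0.878; genes are not independent replicates). Tumour-sorted samples also held RNA of other lineages, with an immune list level of up to 6.09 (tumour A, above the 5.83 and 5.88 of the immune-sorted libraries of tumour C) and a fibroblast list level of up to 5.85 (tumour B). The immune-sorted library of tumour D labelled mechanical and enzymatic was at 4.86 on the epithelial list, above the tumour-sorted libraries of tumours A, B and F (3.85 to 4.73).

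**Figure D1:**
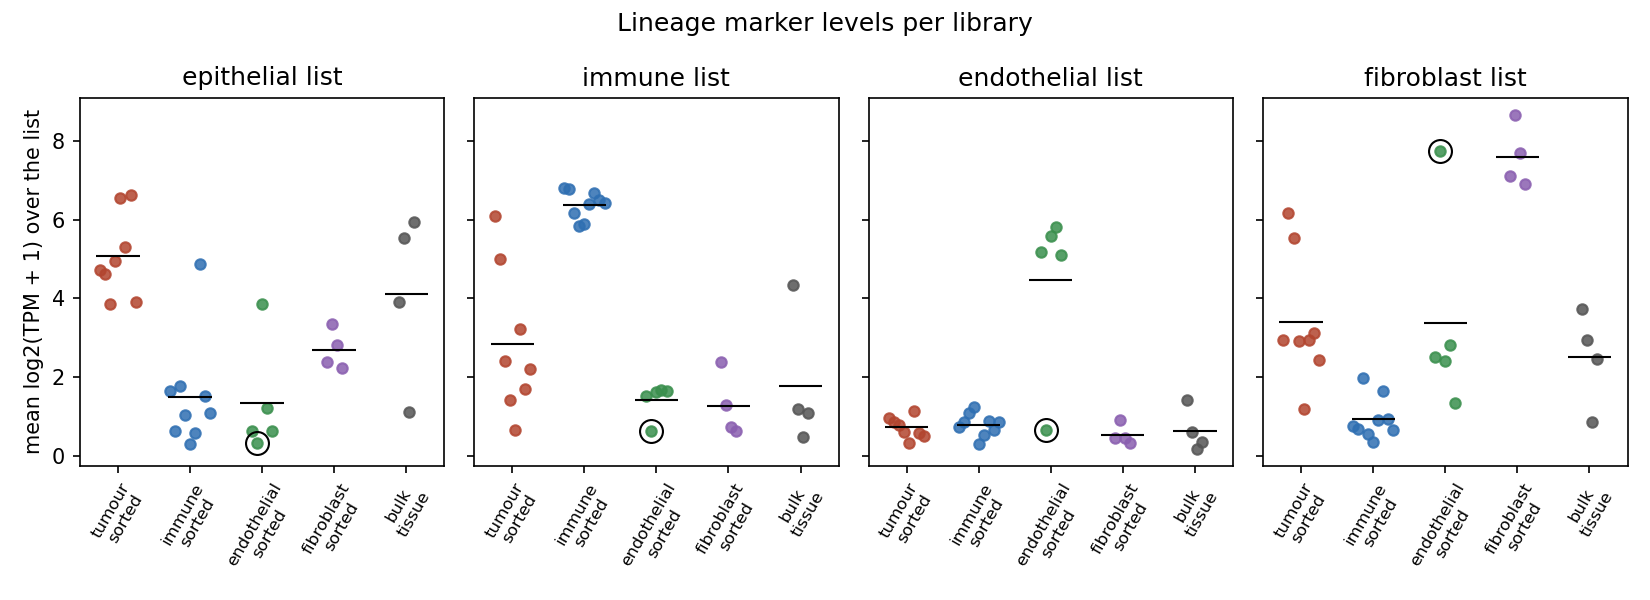
Mean log2(TPM + 1) over the epithelial, immune, endothelial and fibroblast lists (vertical axis), 1 point per library, by sorted population or bulk tissue, with black lines at the group means. The circled point is the library labelled endothelial of tumour C, at 0.65 on the endothelial list and 7.74 on the fibroblast list.

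Tumour-sorted samples were compared with the mean of the other sorted populations to find the genes that mark them. Keratins led the higher genes, among them KRT5 (log2 fold change 4.99 ± 0.56, SE, higher in 6 of 6 tumours; limma adjusted p = 0.000226) and KRT17 (4.32 ± 0.59; limma adjusted p = 0.000974), which are intermediate filament proteins of squamous epithelium. All 24 measured genes of the epithelial list rose (limma), as did 7 of the 19 squamous differentiation genes, such as CALML3 by 2.45 ± 0.36 and TGM1, a transglutaminase of the cornified envelope, by 1.74 ± 0.30. Both lists passed camera with its preset correlation (adjusted p = 1.09e-47 and 6.58e-13) and with an estimated correlation (adjusted p = 0.0149 and 0.0459). Of 13 mitochondrially encoded genes 7 rose (13 adjusted over the list alone), including MT-CO2 by 1.51 ± 0.31; camera gave adjusted p = 4.88e-13, and adjusted p = 0.256 with an estimated correlation. Mitochondrial genes held 23.6% of the TPM in the tumour-sorted library of tumour A and 23.0% in the mechanical one of tumour E, against at most 11.9% in the others. MT-CO2 was at 1.32 without tumour A and 1.35 without that mechanical library, and did not pass without tumour B, D or F (limma adjusted p = 0.0584, 0.09 and 0.121) or without the tumour block (0.0891). The calprotectin genes S100A8 (3.40 ± 0.77) and S100A9 (3.14 ± 0.69) rose as well. The neutrophil list, which holds both genes, ranged from 1.01 (tumour C) to 5.43 (tumour A) in tumour-sorted samples. Its highest level in immune-sorted samples was 4.69 (tumour A).

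Lower genes in the tumour-sorted samples included the kinase FYN (log2 fold change -2.98 ± 0.44; limma adjusted p = 0.00173), the chemokine CXCL13 (-2.60 ± 0.59), the endothelial receptor ENG (-2.54 ± 0.44) and the transcription factor ZEB1 (-2.43 ± 0.31), each lower in 6 of 6 tumours. Of 20 T cell genes 7 fell and 13 did not pass (18 fell adjusted over the list alone), with CD3D at -1.50 ± 0.18 (limma adjusted p = 0.000342) and TRBC1 at -1.43 ± 0.24; camera gave adjusted p = 1.20e-14, and adjusted p = 0.128 with an estimated correlation. The immune and fibroblast lists had no member that passed limma, beside the immune and fibroblast RNA in tumours A and B given above; of the endothelial list 1 gene of 20, ENG, fell. In all, limma called 536 of 18284 genes (334 higher, 202 lower), and 221 of them were more than 1 log2 unit above each other population. The count was 112 over libraries with no enzymes in the label, 345 without the tumour block, 146 without tumour D and 165 without tumour F.

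Immune-sorted samples had the most called genes of the 4 populations. T cell receptor genes TRBC2 (log2 fold change 5.35 ± 0.41; limma adjusted p = 6.62e-07) and TRAC (5.21 ± 0.40), the leukocyte phosphatase PTPRC (5.32 ± 0.47) and the macrophage complement genes C1QB (5.50 ± 0.77) and C1QC (5.47 ± 0.74) were higher in 6 of 6 tumours. Every measured gene of the immune, T cell, and monocyte, macrophage and dendritic cell lists rose (20 of 20 in each; limma). Of 18 checkpoint and regulatory T cell genes 16 rose, with TIGIT at 3.53 ± 0.23 and CTLA4 at 3.99 ± 0.30, both inhibitory receptors, and FOXP3, the regulatory T cell factor, at 3.16 ± 0.21. Of the cytotoxic genes 19 of 20 rose, such as GZMA by 4.16 ± 0.27, and of the 18 B cell and plasma cell genes 14 rose, such as MS4A1 by 2.46 ± 0.46, and 1 fell. Of 25 NF-kB and cytokine genes 8 rose, with TNF at 2.84 ± 0.24 and CCL4 at 4.79 ± 0.49.

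Matrix genes led the lower genes of the immune-sorted samples: COL1A1 (log2 fold change -6.16 ± 1.10; limma adjusted p = 0.00101), COL3A1 (-5.95 ± 0.99) and SPARC (-5.64 ± 0.70) were lower in 6 of 6 tumours. Of the fibroblast list 19 of 20 fell, of the epithelial list 19 of 24, with PERP at -2.29 ± 0.28, and of the endothelial list 2 of 20. With an estimated correlation, camera kept the T cell, checkpoint and leukocyte adhesion lists (adjusted p = 0.0198 each). It did not keep the immune list (adjusted p = 0.123 with an estimated correlation), the cytotoxic list (adjusted p = 0.0533), the B cell list (adjusted p = 0.322), the NF-kB list (adjusted p = 0.356), the monocyte list (adjusted p = 0.132), the fibroblast list (adjusted p = 0.161) or the epithelial list (adjusted p = 0.134). In all, limma called 3722 genes (2320 higher, 1402 lower), of which 1146 exceeded each other population by more than 1 log2 unit. Without libraries that name enzymes the count was 1827, and without tumour B it was 2419.

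Endothelial-sorted samples were compared in the same way, with the library labelled endothelial of tumour C included under its label. Basement membrane genes COL15A1 (log2 fold change 4.38 ± 0.37; limma adjusted p = 5.23e-05), HSPG2 (4.10 ± 0.57) and COL4A1 (3.83 ± 0.57) were higher in 4 of 4 tumours, as was the water channel AQP1 (4.37 ± 0.83). These 4 include tumour C, so the rule for named genes left out genes that were not higher in its library. That library was at 0.156 TPM for VWF and 0.19 for PECAM1, against means of 366 and 144 in the other endothelial tumours. All 20 genes of the endothelial list rose, with the transcription factor ERG at 3.80 ± 0.43 and the receptor ROBO4 at 4.02 ± 0.51. Of 16 tip cell and vein genes 10 rose, such as ESM1 by 2.55 ± 0.32 and DLL4 by 2.76 ± 0.48, and of 7 lymphatic genes 5 rose, such as FLT4 by 2.78 ± 0.44 and MMRN1 by 3.70 ± 0.61. Lower genes included LCP1 of leukocytes (-3.62 ± 0.63; limma adjusted p = 0.00486) and KRT17 (-3.49 ± 0.67). Of the T cell list 15 of 20 fell, of the immune list 14 of 20, of the epithelial list 10 of 24 and of the fibroblast list none. Camera called all of these lists but the fibroblast list with its preset correlation, and none with an estimated correlation (adjusted p = 0.0857 for the endothelial, T cell, tip cell and vein, and lymphatic lists, 0.195 for the immune and 0.101 for the epithelial list). On the fibroblast list the library of tumour C was at 7.74, near the mean of 7.68 in fibroblast-sorted samples. The other endothelial samples were at 2.08 to 2.52, so the absence of fallen fibroblast genes, found with that library included, may not hold for them.

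In all, limma called 865 genes in the endothelial comparison (584 higher, 281 lower; 335 above each other population). Without the library labelled endothelial of tumour C it called 1306, of which 747 were among the 865. Leaving out tumour B gave 126 genes, tumour D 184 and tumour F 78.

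Fibroblast-sorted samples were higher in collagen and small proteoglycan genes, with COL1A1 at a log2 fold change of 7.70 ± 1.41 (limma adjusted p = 0.00939), LUM at 7.31 ± 1.29 and DCN at 7.20 ± 1.25, each higher in 3 of 3 tumours. Of the fibroblast list 19 of 20 rose (20 adjusted over the list alone), with FAP, a surface protease, at 3.73 ± 0.52. Of 16 genes of myofibroblastic cancer-associated fibroblasts 13 rose (16 adjusted over the list alone), such as CTHRC1 by 4.64 ± 0.52, COL11A1 by 4.12 ± 0.49 and LRRC15 by 4.16 ± 0.66. Of 20 matrix metalloprotease and inhibitor genes 5 rose, with MMP11 at 5.60 ± 0.69 and MMP13 at 3.01 ± 0.53, and of 23 partial EMT genes 5 rose, with SNAI2 at 3.63 ± 0.49. Lower genes included the antigen presentation genes HLA-DRA (-3.69 ± 0.80; limma adjusted p = 0.0216) and HLA-DMA (-3.08 ± 0.59). Of the T cell list 8 of 20 fell, of the immune list 3 of 20, of the endothelial list 1 of 20 (PECAM1, -3.37 ± 0.87) and of the epithelial list none. With an estimated correlation the fibroblast, myofibroblastic, metalloprotease, partial EMT and T cell lists had camera adjusted p = 0.1 each, the immune list adjusted p = 0.221 and the endothelial list adjusted p = 0.352.

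In all, limma called 606 genes in the fibroblast comparison (466 higher, 140 lower; 349 above each other population), and the median gene shifted by -0.12 log2 units. Without the library labelled endothelial of tumour C it called 992, of which 605 were among the 606. The count fell to 1 without tumour D and to 4 without tumour F, to 306 without tumour B, and rose to 938 without tumour C. Over the 4 populations, 2051 genes were enriched in 1 population (1303 without tumour D, 1207 without tumour F).

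Bulk tissue was compared with the mean of the 4 sorted populations. Small nuclear and nucleolar RNAs led the higher genes, such as SNORA61 (log2 fold change 6.02 ± 1.06; limma adjusted p = 0.00151) and RNU5E-1 (6.01 ± 0.71), and keratins were also higher, with KRT14 at 4.54 ± 0.90 (limma adjusted p = 0.00358) and KRT6A at 3.48 ± 0.95. Of 24 epithelial genes 4 rose (7 adjusted over the list alone) and 20 did not pass; camera gave adjusted p = 5.81e-12, and adjusted p = 0.489 with an estimated correlation. Of 34 immediate early and dissociation response genes 28 fell (32 adjusted over the list alone) and none rose, such as CSRNP1 by -2.51 ± 0.36 and the transcription factor EGR3 by -2.79 ± 0.44; camera gave adjusted p = 4.59e-18, and adjusted p = 0.293 with an estimated correlation. All 13 mitochondrially encoded genes fell, with MT-ND3 at -2.77 ± 0.58 (camera adjusted p = 1.10e-08, and adjusted p = 0.524 with an estimated correlation). Of 20 heat shock genes 5 fell, with HSPA1A at -3.28 ± 0.69, and of 25 NF-kB and cytokine genes 10 fell, with TNFAIP3 at -2.26 ± 0.59 (adjusted p = 0.841 with an estimated correlation for both lists). Bulk tissue of tumour G was at 0.836 on the heat shock list and 0.524 on the NF-kB list, and without it 1 heat shock, 2 NF-kB, 5 mitochondrially encoded and 18 immediate early genes fell and 11 epithelial genes rose. HSPA1A was then at -2.37, and TNFAIP3, at -1.61, no longer passed (limma adjusted p = 0.0980). After rescaling each library to the same protein-coding total, 2 heat shock, 0 NF-kB, 0 mitochondrially encoded and 11 immediate early genes fell and 13 epithelial genes rose (limma). Of the other lineage lists, 2 immune, 1 endothelial and 2 fibroblast genes of 20 each fell.

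In all, limma called 2393 of 19108 genes in the bulk comparison (446 higher, 1947 lower), and the median gene shifted by -0.38 log2 units. The direction of the calls depended on the scaling: after rescaling each library to the same protein-coding total, 2317 genes were higher and 387 lower, with the median gene at 0.19. Only tumours A and F had both bulk and sorted libraries, and a fit with tumour as a block called 379 genes (289 higher, 90 lower), of which 279 were among the 2393. Without bulk tissue of tumour G the fit without a block called 954 (598 higher, 356 lower). The immediate early list averaged 2.44 ± 0.94 (SD, n = 4) in bulk tissue and 4.55 ± 0.39 (SD, n = 19) in sorted samples, and 3.41 ± 0.46 and 4.40 ± 0.43 after the rescaling, a difference of -0.98 (exact two-sided permutation p = 0.000678 over 8855 splits, which take samples of the same tumour as independent). Within tumours, the rescaled level was 3.06 in bulk tissue of tumour A against 3.99 and 4.10 in its sorted samples, and 3.13 in that of tumour F against 3.95 to 4.66.

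**Figure D2:**
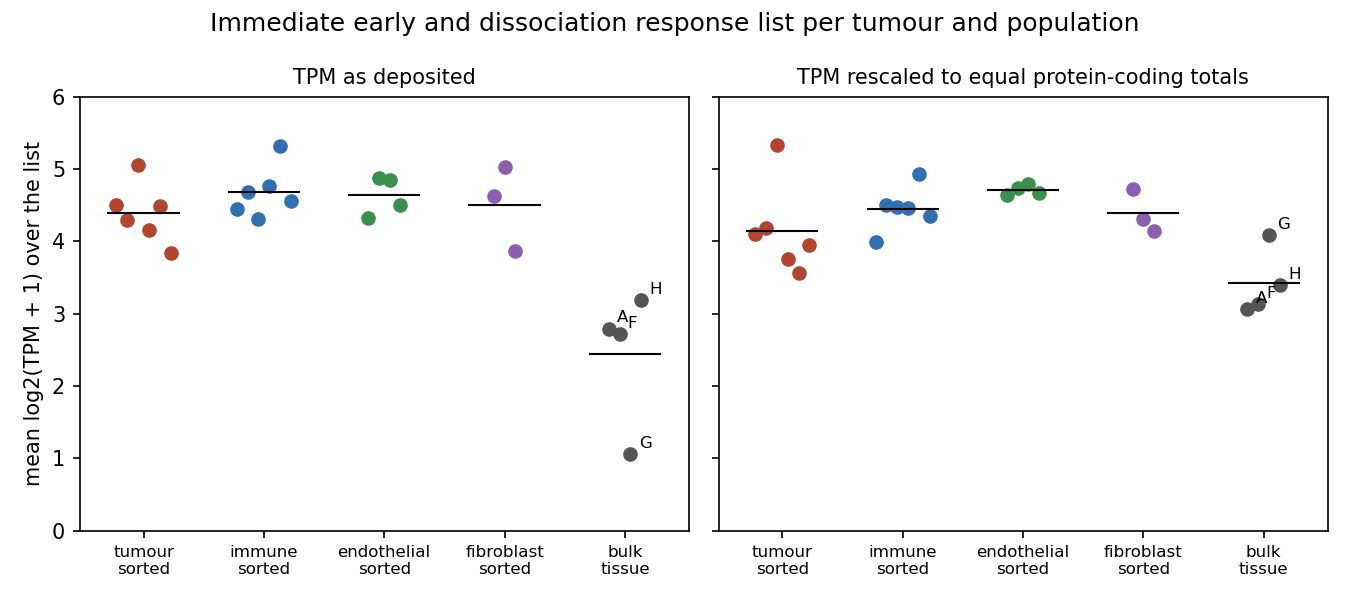
Mean log2(TPM + 1) over the immediate early and dissociation response list (vertical axis), 1 point per tumour and population, as deposited and after rescaling each library to the same protein-coding total, with black lines at the group means and letters naming the bulk tumours. Bulk tissue averaged 2.44 as deposited and 3.41 after rescaling.

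Dissociation was compared within 7 pairs of libraries of the same tumour and population, 1 labelled with enzymes and 1 not. The smallest p-values were those of inducible chaperones. HSPA1A was higher with enzymes in 7 of 7 pairs (log2 difference 2.32 ± 0.36; limma adjusted p = 0.57) and so was its near-identical neighbour HSPA1B (3.23 ± 0.53; limma adjusted p = 0.57); the split of reads between these copies is uncertain. Neither passed the test over all genes, nor did the co-chaperone DNAJB1 (1.97 ± 0.37), the Notch target HES1 (1.78 ± 0.36) or, in the other direction, TXNIP (-1.01 ± 0.25). Adjusted over the list alone, 10 of 20 heat shock genes were higher and none of the 34 immediate early genes passed. Camera gave the heat shock list adjusted p = 6.19e-17, and adjusted p = 0.561 with an estimated correlation.

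The mean of the heat shock list was higher with enzymes in 7 of 7 pairs, by 0.97 ± 0.80 (SD, n = 7; exact two-sided sign-flip permutation p = 0.0156, the smallest that 7 pairs can give). Adjusted over the 34 lists tested, that exact p was 0.482. With the median over the list in place of the mean, the difference was 0.49, higher in 5 of 7 pairs (exact permutation p = 0.0938). The immediate early list differed by 0.79 ± 1.06 (SD, n = 7), higher in 5 of 7 pairs (exact permutation p = 0.125), and after protein-coding rescaling by 0.96 ± 0.94, higher in 6 of 7 (exact permutation p = 0.0312, not adjusted over the lists, with a rescaling chosen after the data were seen). The epithelial list differed by 0.80 ± 1.77 (SD, n = 7; exact permutation p = 0.312), the immune list by -0.67, the endothelial list by 0.02 and the fibroblast list by -0.07. In both tumour-sorted pairs the immune list was lower with enzymes, by -2.60 (tumour B) and -1.53 (tumour E). In all 3 immune-sorted pairs the epithelial list was higher with enzymes, by 1.14, 0.75 and 4.29, as were the fibroblast list (1.29, 0.20 and 0.75) and the endothelial list (0.251, 0.957 and 0.365). Over all 7 pairs limma called 0 of 15672 genes (640 at unadjusted p under 0.05), with the median gene at -0.11.

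**Figure D3:**
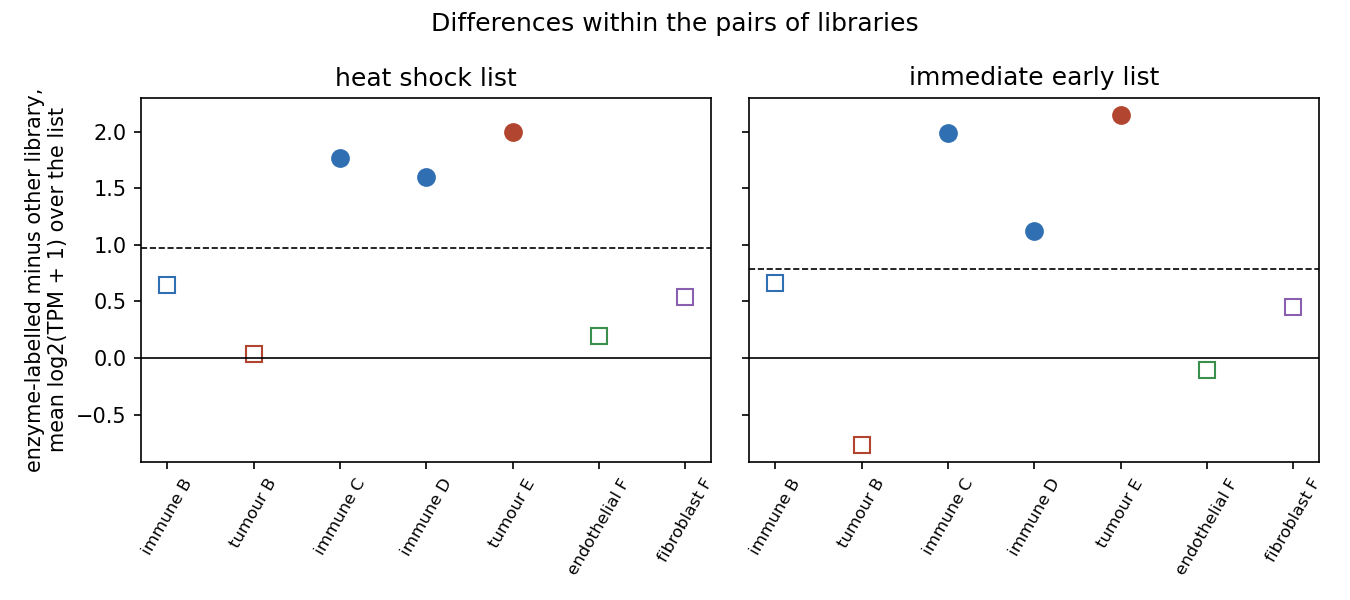
Difference between the enzyme-labelled and the other library of each pair (vertical axis, mean log2(TPM + 1) over the list) for the heat shock and immediate early lists, 1 point per pair. Filled circles are the 3 pairs with both methods stated, open squares the 4 pairs with 1 method not stated, and dashed lines the means of 0.97 and 0.79.

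In the 3 pairs that compared enzymes with mechanical dissociation alone (immune C, immune D and tumour E), both stress lists were higher in 3 of 3 pairs. These pairs mix treatments: the enzyme-labelled library was labelled enzymatic in immune C, and mechanical and enzymatic in immune D and tumour E. The heat shock list was higher by 1.79 ± 0.20 (SD, n = 3; exact permutation p = 0.250, the smallest possible) and the immediate early list by 1.75 ± 0.55 (SD, n = 3; exact permutation p = 0.250). Adjusted over the list alone, 14 of 20 heat shock genes and 26 of 34 immediate early genes were higher, with DNAJB1 at 2.95 ± 0.40, EGR1 at 2.53 ± 0.33 and ATF3, a stress-induced transcription factor, at 4.41 ± 0.70. Of 24 epithelial genes 18 were higher, adjusted over the list alone. With an estimated correlation, camera gave adjusted p = 0.0719 for the heat shock, 0.601 for the immediate early and 0.756 for the epithelial list. Over all genes limma called 0 (1712 at unadjusted p under 0.05; smallest adjusted p = 0.127), with the median gene at 0.19. On simulated data, 30.3% of genes changed by 3 log2 units, all with a mean level at or above the median, were recovered with 3 pairs.

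In the 4 pairs in which 1 label named no method (immune B, tumour B, endothelial F and fibroblast F), the heat shock list was higher in 4 of 4, by 0.35 ± 0.29 (SD, n = 4; exact permutation p = 0.125, the smallest possible). In each of these pairs the enzyme-labelled library was labelled enzymatic alone. With the median over the list in place of the mean, the heat shock difference was 0.0358, higher in 2 of 4 pairs (exact permutation p = 0.75). HSPA1A (1.74 ± 0.40) and HSPA1B (2.19 ± 0.54) were among the 3 heat shock genes that passed adjusted over the list alone. The immediate early list was higher in 2 of 4 pairs, by 0.06 ± 0.64 (SD, n = 4; exact permutation p = 1). Over all genes limma called 0 (826 at unadjusted p under 0.05; smallest adjusted p = 0.226), with the median gene at -0.32; with array weights it called 2, without the pair block 1, and without the tumour E pair 2. Across 15672 genes the mean differences of the 3 and the 4 pairs correlated at r = 0.02 (exact permutation p = 0.688 over 128 sign arrangements; genes are not independent replicates).

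The enzyme effect in the 3 immune pairs was compared with that in the other 4 pairs. HSPG2 (difference of log2 differences 2.61 ± 0.46), NR4A2 (3.11 ± 0.61) and KRT17 (3.53 ± 0.76) were higher in the immune pairs and did not pass (limma adjusted p = 0.853 each). The epithelial list had 8 of 24 genes higher, adjusted over the list alone (camera adjusted p = 9.97e-10, and adjusted p = 0.609 with an estimated correlation). Over all genes limma called 0 (809 at unadjusted p under 0.05), with the median gene at 0.34, and 14 with array weights.

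Paired libraries of the same tumour and population correlated across genes at a median r of 0.883 (n = 7 pairs, 0.55 to 0.941). The lowest was the tumour E pair, 1 of the 3 with both methods stated. Its mechanical library had 11381 protein-coding genes above 0, the fewest of the 30 libraries, and it ranked 25, the last, in similarity to the other library of the pair, which in turn ranked 1 in similarity to it. Libraries of the same population from different tumours had a median r of 0.831 (73 comparisons), and those of the same tumour but different populations 0.732 (43 comparisons). The partner was the most similar library for 8 of the 14 paired libraries.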

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

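Tests chosen after the result was seen were those on the library labelled endothelial of tumour C and, for the heat shock list, those on epithelial RNA, on the tumour E pair and on enzymatic dissociation. So were the values of the immediate early list without bulk tissue of tumour G. The others were written before they were run, those on the immediate early list after the bulk fit with a tumour block had been seen. Single values were screened over 50 groups of samples, in which chance alone marks about 1 in 20 groups.

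The library labelled endothelial of tumour C stood far from the other endothelial samples, with an endothelial list level of 0.65, a fibroblast list level of 7.74 and an immune list level of 0.63. A mixture of endothelial cells with fibroblasts is argued against, since the 20 endothelial list genes lay at a median of 0.416% of the mean of the other endothelial tumours (quartiles 0.126% and 2.06%). The same genes marked the library in the first place, so the percentages restate its list level and are no separate test. A swap with a fibroblast library of the series is argued against too, since the highest endothelial list level among the libraries labelled fibroblast was 0.91. A candidate explanation is a fibroblast sample under an endothelial label. Across 17722 genes in none of the lists, the library correlated at r = 0.863 to 0.874 with the fibroblast-sorted libraries. Its r was at most 0.816 with any other sorted library (0.769 with another endothelial one). These are most of the genes of the correlation given in the Results, so they restate it and are no separate test. A swap with a sample outside the series stays open.

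The heat shock list was higher in the enzyme-labelled library of 7 of 7 pairs, with an exact permutation p of 0.0156 that became 0.482 when adjusted over 34 lists. A different share of noncoding RNA is argued against as the whole cause, since the mean difference after protein-coding rescaling was 1.16 (exact permutation p = 0.0156). Epithelial RNA carried over cannot be told apart: in the 4 pairs that were not immune the heat shock list differed by 0.693 (SD 0.897) and the epithelial list by -0.15 (SD 0.984), both within their spread, although the tumour E pair was the highest on both, and in the other 3 the epithelial list was lower (-0.754, -0.595 and -0.565) while the heat shock list was higher by 0.0393, 0.191 and 0.541. The mechanical library of tumour E has no part in the other 6 pairs, which differed by 0.798 (6 of 6 higher; exact permutation p = 0.0312, which follows from 7 of 7), but how far it carries the pattern stays open, since the median over the list differed there by 0.357 (exact permutation p = 0.188). A response to enzymatic dissociation may contribute but stays open, since the median over the list differed by 0.0358 in the 4 pairs with 1 method not stated (SD 0.293; higher in 2 of 4), and time, temperature and order of handling are not in the labels.

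The immediate early list was lower in bulk tissue than in sorted samples. A lower share of protein-coding RNA is argued against as the whole cause, since the difference after rescaling was -0.984 (exact permutation p = 0.000678). A higher share of epithelial cells cannot be told apart over all 4 bulk libraries, which lay -0.732 from the tumour-sorted samples (exact permutation p = 0.0619). Without bulk tissue of tumour G the difference was -0.95 (exact permutation p = 0.0357), and 6 of 6 tumour-sorted samples lay above the highest bulk library. In tumours A and F, bulk tissue was at 3.06 and 3.13 and the tumour-sorted samples at 4.10 and 3.95. However, the tumour-sorted samples highest on the epithelial list, those of tumours D and E, had the lowest rescaled levels (3.76 and 3.56). Bulk tissue of tumour H was at 3.39. Leaving out tumour G was chosen after the data were seen, so a higher share of epithelial cells stays open. A response to dissociation and sorting may contribute but cannot be told apart from other differences between bulk and sorted material: 15 of 19 sorted samples lay above the highest bulk library. The bound written beforehand counted samples at the level of bulk tissue against it, but the 4 samples lay below only bulk tissue of tumour G, whose protein-coding share was 0.496%, and 19 of 19 lay above the other 3.

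Other single samples stood apart. The salivary gland list was at 2.80 in the tumour-sorted sample and at 1.26 in the immune-sorted sample of tumour F, against at most 0.57 and 0.26 in the others. The heat shock list was at 6.36 in the immune-sorted sample of tumour E and at 0.836 in bulk tissue of tumour G. That bulk library had a protein-coding share of 0.496% and was also the lowest bulk library on each of the lineage lists. The epithelial list was at 3.86 in the endothelial-sorted sample of tumour D, and its difference within the immune pair of tumour D was 4.29. The enzyme difference of the endothelial list was 0.884 higher in the immune pairs than in the others (exact permutation p = 0.0286, the smallest that 35 splits can give). The NF-kB list (1.71) and the tip cell and vein list (0.935) had the same exact p, and none of the 3 passed adjusted over 34 lists (adjusted p = 0.243).

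Counts of called genes were set against other splits of the samples. For the populations, 100 splits were used, the real one included, with population labels permuted within tumours. The real split gave the most genes in the tumour comparison (536 against at most 82 in the other splits). It also did in the immune (3722 against 3068) and endothelial (865 against 231) comparisons. All labels moved at once, so the other splits mixed the sorted populations, which adds their differences to the spread. The counts therefore argue against labels unrelated to expression, taken over all populations, but cannot exclude chance for a single comparison. For the fibroblast comparison 4 splits, the real one included, gave at least 606 genes, the highest other 796. That share was under 0.05, but by too small a margin for 100 random splits to exclude chance. The count was also 1 without tumour D and 4 without tumour F. For bulk tissue only the real split of 100 gave as many genes (2393 against at most 49 in the others). These splits ignored the tumour and also shuffled the labels of the sorted populations, which adds the differences between populations to the spread. The low counts of the other splits therefore cannot exclude chance for bulk tissue. Samples of a tumour also resemble each other, and the fit with tumour as a block called 379 genes, 289 of them higher and 90 lower. For the 7 pairs, 13 of 64 splits gave as many genes at unadjusted p under 0.05 (640 against at most 1689), so chance was not excluded. Nor was it for the immune pairs against the others (6 of 35; 809 against 1830). Why some splits gave more than 2 times the real count was not tested. The 3 pairs (1 of 4; 1712 against 1374) and the 4 pairs (1 of 8; 826 against 321) have too few splits for a share under 0.05.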

How the results depend on the processing

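Rescaling to protein-coding totals and leaving out the libraries named below were chosen after the data were seen; the other settings were fixed before. Depth is unknown for TPM, so its limits could not be given. Of 4288 values of named genes under alternatives, 3813 kept direction and side of the threshold. A further 452 kept direction but no longer passed, 20 newly passed and 3 reversed. The total includes the pair comparisons, where no gene passed in the main fit, so none could lose its call. With tumours left out in turn, 118 of 198 fibroblast and 128 of 183 endothelial values were kept. In the tumour and immune comparisons, 164 of 198 and 264 of 264 were kept. All 33 named fibroblast genes and 23 of 31 endothelial genes lost their call in some of these fits. The reversed values were TUG1 in bulk tissue, at 0.0553 with the rescaling and 0.0565 with bulk tissue of tumour G also left out, and NORAD at 0.0329 in the latter; neither had passed.

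With no filter, the tumour, immune, endothelial and fibroblast counts were 148, 2324, 205 and 43, and enriched genes 1268; with a filter at 10 TPM, which tests fewer genes, 303, 1855, 503 and 347, and 1174. A pseudocount of 5 gave 289 (tumour), 395 (fibroblast), 875 (enriched) and 1558 (bulk). Libraries without enzymes in the label, which are fewer samples, gave 112 (tumour), 1827 (immune) and 205 (fibroblast). Every library as its own sample gave 911 (fibroblast). Without the library labelled endothelial of tumour C the endothelial count was 1306 and the fibroblast count 992. Without the replicate block the tumour count was 345; with the replicate block the bulk count was 379. Without the pair block, 1 gene was called in the 4 pairs. The block moved no other total of called genes by over 1.5 times, and this does not cover the higher, lower or unadjusted counts. Array weights gave 2 genes in the 4 pairs and 14 in the immune against other pairs. Rescaling with bulk tissue of tumour G left out gave 1480 bulk genes.

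The split of bulk calls into higher and lower moved with scaling, from 446 and 1947 to 792 and 869 (trimmed mean), 1201 and 1170 (quantile) and 2317 and 387 (protein-coding). The immune split moved from 2320 and 1402 to 2093 and 1953 with quantile normalization, and the tumour split was 350 and 317, of 667, with the protein-coding rescaling. Over the comparisons, 136 of 302 list tests passed with the preset and 5 with the estimated correlation. Taken over the median of the list, the pair differences were -0.0276 (endothelial), 0.114 (fibroblast) and 0.49 (heat shock). Leaving out 1 tumour gave 146 to 635 genes (tumour), 2419 to 3523 (immune), 78 to 1223 (endothelial), 1 to 938 (fibroblast) and 1207 to 2280 (enriched). Leaving out 1 bulk library gave 954 to 3391, the lowest without tumour G. Leaving out 1 pair gave 0 to 1 in the 3 pairs and 0 to 2 in the 4 pairs. For each of these changes the cause was not tested.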

Other observations

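The limma tests were fixed before, and which genes to name here was chosen after the result was seen. The partial EMT list split in the tumour-sorted samples: the laminin genes LAMB3 (2.08 ± 0.30) and LAMA3 (1.92 ± 0.34) rose (limma), and in all 4 members rose and 2 fell of 23.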
